A study of Homo sapiens with 15 samples.

How the data were processed

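The series holds RNA sequencing of 15 libraries: 3 each of the lines MCF10A, AT1 and CA1, and 3 each of AT1 cells transfected with a negative control GapmeR or a GapmeR against IGFL2-AS1. Per the labels' protocols, total RNA was extracted with Trizol and Direct-zol columns with DNase I, ribosomal RNA was depleted with Ribo-Zero Gold, and stranded total RNA libraries were amplified with KAPA reagents under real-time monitoring and sequenced as single-end reads. Per the labels' protocols, MCF10A and AT1 were grown with horse serum, insulin, EGF, cholera toxin and hydrocortisone, and the CA1 medium lists no insulin, EGF, cholera toxin or hydrocortisone. The transfected cells received 10 nM of GapmeR and were taken after 48 h, per the labels. Per the submitters' processing notes, the tools were cutadapt 1.6, TopHat2, HTSeq 0.6 and DESeq2 1.8.1 in R 3.2.0, with the hg38 genome. The version of TopHat2 and the use of strand in counting are not given in the sources used here. The deposited values are normalised read counts (signal) per gene, in 1 table for the 9 libraries of the lines and another for the 6 transfected libraries, per the labels. The tables were normalised separately, and levels set across them carry that limit.

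Whole reads were recovered by finding, for each library, the factor that turns its values into whole numbers, and 100% of values were whole within 0.01. The factors of CA1 replicate 1 and control GapmeR replicate 3 were near 1. Recovered depth in units of 1e6 reads was 14.5, 12.9 and 28.7 for MCF10A, 24.1, 15.6 and 16.3 for AT1, 19.0, 25.5 and 18.0 for CA1, 20.6, 21.0 and 22.0 for the control GapmeR, and 32.0, 26.4 and 17.9 for the IGFL2-AS1 GapmeR. Genes were named and classed with the HGNC and RefSeq (GRCh38.p14) tables provided. Of 18213 genes in the table of the lines, 16263 had a symbol and 16163 (88.7%) a RefSeq class, and 1218 were lncRNAs, 37 of them by name only. For the transfected cells these were 17785, 15958, 15867 (89.2%), 1171 and 31. Genes with no class, 2013 in the lines and 1887 in the transfected cells, were counted with the other genes wherever lncRNAs were set beside them.

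The main test was limma-trend (limma 3.58.1, R 4.3.3) on log2(value + 1) for genes with a mean value of at least 10, with a false discovery rate of 0.05 by Benjamini and Hochberg. The 9 libraries of the lines shared 1 fit, and the 6 transfected libraries another. Whether replicate numbers pair libraries was checked by correlating deviations from the group mean, with 0.1 as the threshold. In the transfected cells, same-number libraries had correlations of 0.611, 0.568 and 0.651 and the highest other values were -0.068, -0.018 and -0.387. A replicate block was therefore run beside the unblocked fit, as planned before the data were examined. edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads.

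The 26 gene lists were fixed before the data were examined, and cover RAS-MAPK output, basal, luminal, mesenchymal, epithelial junction, epidermal differentiation, mitotic, DNA replication, histone, cholesterol, interferon, NF-kB, p53, unfolded protein, hypoxia, protease, glucocorticoid, cAMP-CREB, insulin-FOXO and TGF-beta genes. The others were textbook cancer lncRNAs, mitochondrially encoded mRNAs, the IGFL family, and fibroblast, haematopoietic and endothelial markers. The 22 lists with at least 5 tested members were tested with camera (preset correlation 0.01), and again with an estimated correlation and with fry. Lists were written from general knowledge and are not a curated database. Adjusted p-values for lists cover the lists of 1 comparison.

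Named genes followed a rule fixed before the data were examined: per comparison, the 8 protein-coding genes with the largest rise and the 8 with the largest fall among those past the threshold, with groups that did not overlap and a mean of at least 50 in the higher group. The rule added 4 lncRNAs per direction with a mean of at least 20, up to 2 genes per list and direction, HRAS, the IGFL2-AS1 locus, and 3 line-selective lncRNAs per line. In the transfected cells no gene passed without the block, and the rule was applied to the blocked fit with all 3 pairs moving in 1 direction in place of groups that do not overlap, a choice made after the data were examined. Genes cited for the cell-type lists were chosen after their values were seen. A fold against a group at 0 is a floor, taken at 3 counts over that group, and a group with 1 to 3 counts has a ratio with its 95% counting interval.

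Line-selective lncRNAs were those higher, with a false discovery rate of 0.05 and at least 2-fold, in 1 line than in each of the others, and their share was set beside that of other genes within 10 classes of mean expression by the Cochran-Mantel-Haenszel test. The overlap of both comparisons with MCF10A was set beside 100 simulated draws with no line effect. A first form redrew each library's residuals with replacement, and it can give a group 3 identical libraries. The other forms, with independent or weighted residuals, were added after this was seen, and all 3 are reported.

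The test was tested on simulated data with 100 genes per size of change. For 4-fold changes it recovered 82%, 77% and 63% in the comparisons of the lines, 54% in the transfected cells and 92% there with the block. For 2-fold changes it recovered 21%, 11% and 9%, then 10% and 75%. Unchanged genes made up 6.4%, 6.4%, 2.7%, 0% and 4.6% of its calls, and 25.8%, 21.5%, 31.4% and 0% of those of DESeq2 without the block. A changed list was called in every case and 0 of 20 unchanged lists were. Noise was drawn gene by gene and unchanged lists were random genes, so this does not test lists whose members move together. Each gene also had the same dispersion in every group, so the shares of false calls do not cover groups of unequal spread. In the data, mitotic medians were 1630, 26.13 and 1702 in MCF10A, against 2283, 2124 and 2238 in AT1.

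Analyses also tried other pseudocounts, no filter or a mean of at least 50, TMM and upper-quartile rescaling, no or a robust mean-variance trend, edgeR, DESeq2, the replicate block, camera with an estimated correlation, fry, a 2-fold threshold, lncRNAs classed by name only, fits on only the libraries of the lines compared, and leaving out each library, all chosen before the data were examined. Lists and overlaps without MCF10A replicate 2, lists from only the CA1 and AT1 libraries, simulated line-selective counts and all alternatives to the blocked fit were chosen after seeing the data. Raw reads, isoforms and splicing were not analysed here. Results for some single genes that the naming rule covers are not reported here.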

Results

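RNA sequencing of total RNA covered 3 related human breast lines: the non-tumorigenic line MCF10A, its HRAS-transformed derivative MCF10A-AT1 (AT1), and MCF10A-CA1 (CA1, given as MCF10CA1a in the labels' growth protocol), a derivative known to form carcinomas. Each line had 3 libraries in 1 table of normalised read counts, with between 12.9e6 and 28.7e6 recovered reads per library. A separately normalised table held AT1 cells 48 h after transfection with 10 nM of a negative control GapmeR or of a GapmeR against the long noncoding RNA (lncRNA) IGFL2-AS1, with 3 libraries each and between 17.9e6 and 32.0e6 reads. The series asks which lncRNAs are selective for a stage of this progression, and what follows when IGFL2-AS1 is depleted. Tests covered 16239 genes (886 of them lncRNAs) in the lines and 16217 genes (905 lncRNAs) in the transfected cells. Fold changes are on the scale of log2(value + 1) and understate the change of low genes, values with ± are mean and SD of 3 libraries, and intervals and floors on ratios cover counting error only. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. CA1 was grown without the insulin, EGF, cholera toxin and hydrocortisone given to MCF10A and AT1, so line and medium are not separable in either comparison with CA1.

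MCF10A replicate 2 stood apart from the other MCF10A libraries. The median value of 24 mitotic genes was 26.13 in it, 1630 in replicate 1 and 1702 in replicate 3, and that of DNA replication genes was 93.92 against 577.3 and 891.8. Histone genes had a median of 118.6 against 820 and 2002, and mitochondrially encoded mRNAs 596 against 1807 and 1682. The small nuclear RNA RN7SK took 3.19% of its reads, against 2.12% and 1.11%.

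HRAS, the oncogene that defines AT1, rose at each step. Its level was 507 ± 157 in MCF10A, 2958 ± 258 in AT1 and 6535 ± 464 in CA1 (n = 3 each). The log2 change was 2.59 from MCF10A to AT1 (adjusted p = 8.97e-05), 3.73 from MCF10A to CA1 (adjusted p = 6.97e-06) and 1.15 from AT1 to CA1 (adjusted p = 0.00741). IGFL2-AS1, an antisense lncRNA beside the genes of the IGF-like growth factors, fell at each step in the untransfected lines. It measured 800 ± 782 in MCF10A (1701, 292 and 407 in the 3 libraries), 54.8 ± 9.01 in AT1 and 3.86 ± 1.66 in CA1, with log2 changes of -3.41 (adjusted p = 0.00275), -6.99 (adjusted p = 5.62e-05) and -3.58 from AT1 to CA1 (adjusted p = 0.00451). In AT1 with the control GapmeR, normalised separately, IGFL2-AS1 measured 375.6, 505.1 and 776.7, within the range of the MCF10A libraries. So its low level in untransfected AT1 was not seen in transfected AT1. IGFL2-AS1 lies inside the annotated span of IGFL2, and whether counting used the strand is not stated, so reads of these genes may be shared.

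**Figure D1:**
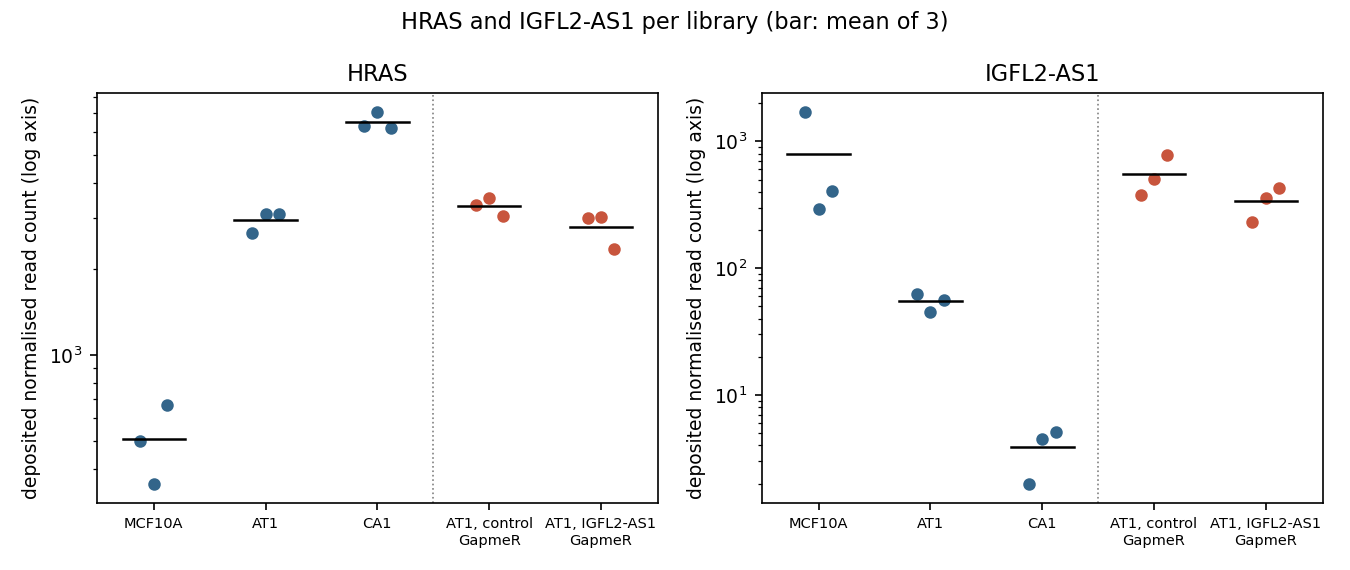
HRAS and IGFL2-AS1 as the deposited normalised read count (log axis) in each library, with dots for libraries and bars for the mean of 3, blue for the lines and red for the transfected AT1 cells, and a dotted line between the separately normalised tables. HRAS rose from 507 in MCF10A to 6535 in CA1, while IGFL2-AS1 fell from 800 to 3.86.

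The first comparison asked how HRAS-transformed AT1 differed from MCF10A. The largest rise was in FBN2, which encodes the microfibril protein fibrillin 2: 2200 ± 181 in AT1 and 0 in MCF10A, at least 2220-fold (log2 11.1, adjusted p = 1.84e-09). Also absent from MCF10A were the zinc-finger gene ZC4H2 (89.9 ± 6.63 in AT1, at least 91-fold), the Polycomb-associated SFMBT2 (81.8 ± 11.9, at least 82.7-fold) and SUSD5 (51.5 ± 8.14, at least 51.3-fold). The protease inhibitor SERPINB13 rose from 4.92 ± 7.98 to 244.7 ± 36.5 (log2 6.39), and the growth-factor binder IGFBP7 from 57.9 ± 66.9 to 963.4 ± 12.8 (log2 5.75, adjusted p = 0.0135). IL13RA2, the decoy receptor for interleukin 13, rose to 113.5 ± 12.9 (ratio 116, interval 39.3 to 564).

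The largest fall was in CYBA, a subunit of the NADPH oxidase, from 2694 ± 1060 to 1.11 ± 1.1 (log2 -10.41, adjusted p = 1.16e-05). AZGP1, a secreted glycoprotein of differentiated epithelia, fell from 9965 ± 7860 to 12.3 ± 8.57 (log2 -9.34), and the retinoid-responsive RARRES1 from 34390 ± 29700 to 46.2 ± 2.17 (log2 -9.15, adjusted p = 1.49e-05). FOXI1, a transcription factor of proton-secreting cells, fell from 410.7 ± 80.1 to 0 (at least 454-fold), and ATP6V1B1, a proton-pump subunit of such cells, from 2424 ± 2010 to 4.11 ± 2.76 (log2 -8.74). The potassium channel KCNK15 fell 1010-fold (interval 280 to 8360), TMEM45B 1050-fold (interval 291 to 8700), and the netrin receptor UNC5C from 1082 ± 729 to 1.61 ± 1.87 (log2 -8.57).

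Among lncRNAs, MYOSLID, known from smooth muscle, rose from 12.6 ± 12.9 to 321.5 ± 20.7 in AT1 (log2 5.17, adjusted p = 0.000884), and LINC00941 from 10.6 ± 13.5 to 220 ± 25.8 (log2 4.98). NRAD1 fell from 466.6 ± 562 in MCF10A to 0 (at least 424-fold), ITGB8-AS1 from 723.8 ± 173 to 14.9 ± 7.19 (log2 -5.61), UCA1 from 493.6 ± 397 to 7.72 ± 3.66 (log2 -5.59) and LINC01559 from 169.8 ± 81 to 2.74 ± 0.794 (log2 -5.41).

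Epithelial and mesenchymal lists were compared between AT1 and MCF10A. Of 23 epithelial junction genes, 13 fell and 2 rose (adjusted p = 0.000183 for the list, adjusted p = 0.205 with an estimated correlation). The adherens-junction cadherin CDH1 fell from 17900 ± 4080 to 3238 ± 243 (log2 -2.45, adjusted p = 3.83e-05) and the tight-junction gene TJP3 from 1482 ± 747 to 13.3 ± 3.68 (log2 -6.56). Of 14 luminal markers, 5 fell and 2 rose (adjusted p = 0.0163, and adjusted p = 0.205 with an estimated correlation): ELF3 fell to 317.7 ± 38.4 from 8978 ± 5140 (log2 -4.63), AGR2 had log2 -6.72, and KRT18 rose (log2 0.76). Leaving out MCF10A replicate 2, 10 luminal markers fell. Of 17 mesenchymal genes, 7 rose and 1 fell (adjusted p = 0.0188, and adjusted p = 0.59 with an estimated correlation). The intermediate filament gene VIM rose from 269 ± 184 to 6573 ± 361 (log2 5.02, adjusted p = 0.000499), while SNAI1, a repressor of CDH1, fell (log2 -3.11). Epidermal differentiation genes fell at 7 of 18 with none higher, such as TGM1 (log2 -2.10) and KLK5 (log2 -4.55) (adjusted p = 0.0291, and adjusted p = 0.317 with an estimated correlation). Of 19 basal markers, 3 rose, such as KRT14 (log2 2.39) and ITGA6 (log2 1.53), and 2 fell (adjusted p = 0.362), against 5 and 5 without MCF10A replicate 2. Junction medians were 2978 to 3369 in MCF10A and 1075 to 1271 in AT1, but 3479, 3770 and 2357 in AT1 with the control GapmeR. Luminal medians were 1362 to 2623, 286.8 to 335.2, and 1431, 1132 and 1610. So AT1 cells of the separately normalised table did not show junction and luminal falls of this size.

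Targets of several signals also moved. Of 25 RAS-MAPK output genes, 11 rose and 2 fell (adjusted p = 0.00666, and adjusted p = 0.59 with an estimated correlation). The ERK phosphatase DUSP7 rose from 333.8 ± 63.4 to 1685 ± 227 (log2 2.34) and PHLDA1 from 3591 ± 359 to 8202 ± 635 (log2 1.19), while the feedback inhibitors SPRY2 (log2 -1.08) and DUSP4 (log2 -1.40) fell. Unfolded protein and amino acid response genes rose at 13 of 22 and fell at 4 (adjusted p = 0.00276, and adjusted p = 0.523 with an estimated correlation), with TRIB3 up from 401 ± 144 to 6672 ± 1000 (log2 4.12) and CHAC1 at log2 4.82. Targets of FOXO, which insulin restrains, fell at 10 of 15 with none higher (adjusted p = 0.000337, and adjusted p = 0.205 with an estimated correlation), among them FBXO32 from 5424 ± 3720 to 257 ± 25.2 (log2 -4.16). Of 20 hypoxia and glycolysis genes, 7 rose and 1 fell (adjusted p = 0.0384, and adjusted p = 0.261 with an estimated correlation), with HK2 at log2 2.17. For hypoxia genes, 11 rose without MCF10A replicate 2. RAS-MAPK medians were 145 to 646.6 in MCF10A, 925.5 to 1090 in AT1, and 472.9 to 606.6 in AT1 with the control GapmeR. In the same order, unfolded protein medians were 787.3 to 2141, 3114 to 3719, and 1229 to 2290. Hypoxia medians were 730.7 to 1329, 1538 to 1793, and 939.3 to 1315. AT1 cells of the separately normalised table thus did not show rises of this size in these lists. FOXO medians stayed lower there, at 698.9 to 1425 against 1479 to 2049 in MCF10A.

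Interferon-stimulated genes fell at 8 of 23 and rose at 1, OAS3 (log2 2.24) (adjusted p = 0.0188, and adjusted p = 0.562 with an estimated correlation). The falls included IFI44 (log2 -2.58) and the RNA sensor IFIH1 (log2 -1.90), and the list lost its call (adjusted p = 0.122) without MCF10A replicate 2, whose median interferon level was 141.2 against 40.44 and 50.18. NF-kB and inflammatory genes split, 7 rising and 6 falling of 21 (adjusted p = 0.704), with IL1A up from 34.2 ± 12.7 to 557.9 ± 44.9 (log2 4.06), LCN2 down from 387.4 ± 243 to 4.63 ± 2.06 (log2 -5.92) and the list's median and mean on opposite sides of 0. TGF-beta targets were 4 up and 4 down of 19 (adjusted p = 0.629), with ITGB6 at log2 -3.83 and LTBP2 at log2 1.01. Of 20 glucocorticoid-induced genes 8 rose, such as MT1X (log2 2.72) and RGS2 (log2 1.86), and 2 fell (adjusted p = 0.0662), against 8 and 6 without MCF10A replicate 2 (adjusted p = 0.358). Matrix proteases and inhibitors rose at 6 of 17 and fell at 3 (adjusted p = 0.165), with TIMP1 at log2 2.27 and SERPINB2 at log2 -3.94. Among p53 targets 3 rose and 5 fell of 22 (adjusted p = 0.498), SESN2 at log2 1.75 and TP53INP1 at log2 -3.13, against 5 and 7 without MCF10A replicate 2. Of 17 cAMP-CREB targets 3 rose and 4 fell (adjusted p = 0.31), NR4A1 at log2 -5.80. Textbook cancer lncRNAs gave 8 up and 6 down of 32 (adjusted p = 0.498), with MIR31HG at log2 2.55 and NEAT1 at log2 -1.33. Unlike camera, fry called proteases (adjusted p = 0.0047) and glucocorticoid-induced genes (adjusted p = 0.0161) higher and TGF-beta targets lower (adjusted p = 0.0066). It did not call the mitotic (adjusted p = 0.199) or DNA replication (adjusted p = 0.166) lists.

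Growth genes moved with MCF10A replicate 2. The 24 mitotic genes had a median log2 of 2.40 and no member passed, although the list was called (adjusted p = 0.00666, and adjusted p = 0.644 with an estimated correlation). The mitotic median was 0.37 without MCF10A replicate 2, with 13 members higher and 1 lower. FOXM1, which drives mitotic transcription, measured 2125 ± 92.5 in AT1 and 525 ± 471 in MCF10A (log2 3.41, adjusted p = 0.0658), and log2 1.47 with adjusted p = 0.000159 without that library. Leaving out MCF10A replicate 1 or 3 also gave FOXM1 a call (adjusted p = 0.0487 and 0.0225). Of 26 DNA replication genes 5 rose (adjusted p = 0.00276, and adjusted p = 0.644 with an estimated correlation), 0 did adjusted over the list alone, and without that library 8 rose and 1 fell with a median of 0.42 in place of 1.367. The replication genes TYMS (log2 2.64, adjusted p = 0.0283) and POLA1 (log2 1.23, adjusted p = 0.0366) both lost their call without any 1 of the AT1 libraries (adjusted p up to 0.0788 and 0.101).

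Histone and mitochondrial lists were called higher in AT1 by camera. Replication-dependent histone genes rose at 18 of 21 (adjusted p = 4.45e-05, and adjusted p = 0.562 with an estimated correlation), with H1-4 up from 4842 ± 1850 to 14510 ± 3190 (log2 1.63). The histone median was 1.58 in place of 2.27 without MCF10A replicate 2, with 18 rising. Many histone genes have similar copies, so values of single histone genes may be uncertain. Mitochondrially encoded mRNAs rose at 7 of 13 (adjusted p = 0.000183, and adjusted p = 0.562 with an estimated correlation), such as MT-ND1 from 492.6 ± 114 to 1849 ± 220 (log2 1.93), and at 9 of 13 without that library. Mitochondrial rRNA took 0.022 to 0.107% of MCF10A reads and 0.75 to 1.043% of AT1 reads, while RN7SK took 1.11 to 3.19% and 0.531 to 0.997%, so the share of RNA classes differed between these libraries. Mitochondrially encoded genes took 0.254 to 0.717% in MCF10A, 1.736 to 2.031% in untransfected AT1 and 0.246 to 0.7% in AT1 with the control GapmeR. Mitochondrial rRNA took 0.013 to 0.114% with the control GapmeR. Untransfected AT1 thus also stood apart from transfected AT1, and line and library preparation were not separable in these shares. Of 23 cholesterol synthesis genes 2 rose, such as MVK (log2 0.81), and 2 fell, such as TM7SF2 (log2 -1.46) (adjusted p = 0.536). Without MCF10A replicate 2 these counts were 5 and 10.

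In all, 6689 genes changed between AT1 and MCF10A by limma with a false discovery rate of 0.05, 3210 higher and 3479 lower, and 324 of them were lncRNAs (171 higher, 153 lower). The groups did not overlap for 51.2% of all tested genes, against 10% by chance. Using only the libraries of this pair gave 4141 genes and 189 lncRNAs, and leaving out AT1 replicate 3 gave 4416 and 206. Adjusted over the lncRNAs alone, 311 changed.

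The second comparison asked how CA1, the carcinoma-forming line, differed from MCF10A. FBN2 was again the largest rise, to 2428 ± 153 from 0 (at least 2410-fold, log2 11.24). The inflammatory cytokine IL1B rose from 17.3 ± 26.7 to 5978 ± 345 (log2 9.92, adjusted p = 0.00022), the glutathione peroxidase GPX2 from 3.88 ± 2.9 to 3230 ± 249 (log2 9.54, adjusted p = 1.18e-06) and SPARC, a matrix-binding glycoprotein, from 10.3 ± 10.1 to 2681 ± 113 (log2 8.43). The enteropeptidase gene TMPRSS15 rose to 2288 ± 87.1 (ratio 6850, interval 1230 to 271000), CALML3 to 932.5 ± 64.5 (ratio 2820, interval 505 to 111000), IL13RA2 to 892.2 ± 14.1 (ratio 890, interval 304 to 4320) and the serine protease PRSS21 to 474.4 ± 51.4 (ratio 718, interval 198 to 5930).

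CYBA fell here too (log2 -10.89, adjusted p = 3.33e-06). MSLN, the surface protein mesothelin, fell from 7974 ± 2030 to 5.26 ± 1.37 (log2 -10.30, adjusted p = 9.18e-08), AZGP1 to 9.28 ± 1.23 (log2 -9.52) and KCNK15 to 0 (at least 720-fold). The transcription factor TSHZ2 fell from 2177 ± 1030 to 2.18 ± 0.819 (log2 -9.31), the sodium channel subunit SCNN1B from 2576 ± 2420 to 1.94 ± 1.17 (log2 -8.89), the selenium carrier SELENOP from 852 ± 349 (ratio 2470, interval 444 to 97800) and the protease KLK7 from 2739 ± 3330 (ratio 2700, interval 923 to 13100). Among lncRNAs, LINC00973 rose from 0.847 ± 1.47 to 574.7 ± 33.3 (log2 8.56) and LINC01239 from 1.27 ± 2.2 to 192.9 ± 16.6 (log2 6.84), while LINC00525 fell from 241.8 ± 30.1 to 5.9 ± 4.4 (log2 -5.38), NRAD1 to 3.58 ± 0.449 (log2 -5.55) and PKD2L2-DT 154-fold (interval 27.3 to 6140).

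Transcripts of the RAS-MAPK list were mostly higher in CA1, and RAS activity itself was not measured. Of 25 RAS-MAPK genes, 19 rose and 1, SPRY2 (log2 -1.25), fell (adjusted p = 7.28e-06, and adjusted p = 0.338 with an estimated correlation). The EGF receptor ligand TGFA rose from 1440 ± 173 to 8245 ± 206 (log2 2.52, adjusted p = 2.86e-06) and DUSP7 to 2464 ± 166 (log2 2.90). NF-kB and inflammatory genes rose at 13 of 21 and fell at 3 (adjusted p = 0.000566, and adjusted p = 0.329 with an estimated correlation): IL1A from 34.2 ± 12.7 to 8633 ± 236 (log2 8.02) and the neutrophil attractant CXCL1 from 24.5 ± 7.31 to 1744 ± 63.7 (log2 6.14), with ICAM1 lower (log2 -3.54). Matrix proteases and inhibitors rose at 9 of 17 and fell at 2 (adjusted p = 0.00117, and adjusted p = 0.123 with an estimated correlation), with the collagenase MMP1 at 106 ± 24.2 from 0 (at least 108-fold) and the urokinase receptor PLAUR at log2 2.06. Hypoxia and glycolysis genes rose at 10 of 20 (adjusted p = 0.00122, and adjusted p = 0.123 with an estimated correlation), such as HK2 to 5551 ± 147 (log2 3.70) and CA9 (log2 3.46).

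Of 22 unfolded protein and amino acid response genes 13 rose, such as TRIB3 to 8694 ± 645 (log2 4.51), and 3 fell, such as DNAJB9 (log2 -1.80) (adjusted p = 0.00177, and adjusted p = 0.338 with an estimated correlation). Glucocorticoid-induced genes fell at 14 of 20 and rose at 3 (adjusted p = 0.00555, and adjusted p = 0.338 with an estimated correlation), such as GLUL from 16800 ± 6920 to 2272 ± 53.3 (log2 -2.78) and DUSP1 from 7023 ± 5400 to 338.6 ± 21.9 (log2 -4.05), in the line grown without hydrocortisone. FOXO targets fell at 9 of 15 and rose at 1 (adjusted p = 0.00068, and adjusted p = 0.166 with an estimated correlation), with PDK4 down from 3664 ± 2110 to 110.9 ± 25.6 (log2 -4.91) and CITED2 from 1656 ± 183 to 224 ± 23.6 (log2 -2.88). For cAMP-CREB targets, 4 rose, such as PTGS2 from 56.7 ± 40.2 to 842.6 ± 27 (log2 4.13), and 6 fell, such as PDE4B (log2 -4.28), of 17 (adjusted p = 0.458).

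Basal markers rose at 11 of 19 and fell at 2 (adjusted p = 0.00848, and adjusted p = 0.298 with an estimated correlation), with KRT6B up from 764 ± 495 to 12840 ± 821 (log2 4.42) and ITGA6 from 9740 ± 4480 to 56330 ± 2150 (log2 2.67). Epidermal differentiation genes rose at 9 of 18 and fell at 3 (adjusted p = 0.0429, and adjusted p = 0.329 with an estimated correlation), with KRT13 up from 11.1 ± 11.2 to 2474 ± 225 (log2 8.06) and TGM1 down (log2 -2.83). That call was lost without MCF10A replicate 2 (adjusted p = 0.075), with 11 rising and 5 falling. Of 14 luminal markers 3 rose, such as KRT18 to 23360 ± 423 from 5286 ± 1240 (log2 2.17), and 7 fell, such as the mucin MUC1 from 1611 ± 1120 to 4.04 ± 1.85 (log2 -8.14) (adjusted p = 0.158), against 5 and 7 without MCF10A replicate 2. Mesenchymal genes gave 3 up, with VIM at 3419 ± 281 (log2 4.08), and 4 down, with FBN1 at log2 -4.71, of 17 (adjusted p = 0.802). Mesenchymal genes fell at 9 and rose at 4 without MCF10A replicate 2. Of 23 junction genes 4 rose, such as JUP (log2 0.83), and 8 fell, such as CDH1 to 6630 ± 105 (log2 -1.41) (adjusted p = 0.154).

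By camera, the interferon, p53, TGF-beta and cancer lncRNA lists had no call. Interferon-stimulated genes rose at 5 and fell at 7 of 23 (adjusted p = 0.91), with OAS3 at log2 2.31 and IFI44L at log2 -3.27. Interferon genes rose at 9 and fell at 7 without MCF10A replicate 2. Among p53 targets 6 rose and 5 fell of 22 (adjusted p = 0.815), such as PHLDA3 (log2 1.06) and RRM2B (log2 -1.55). TGF-beta targets rose at 3 and fell at 6 of 19 (adjusted p = 0.802), such as LTBP2 (log2 1.76) and ID2 (log2 -3.59), against 7 and 7 without MCF10A replicate 2. Textbook cancer lncRNAs rose at 8 and fell at 7 of 32 (adjusted p = 0.458), such as PVT1 (log2 1.65) and CRNDE (log2 -1.26), and fry called that list higher (adjusted p = 0.0146, and adjusted p = 0.014 with the replicate block). Fry also called the luminal (adjusted p = 0.000836) and junction (adjusted p = 0.00835) lists lower. It did not call the mitotic (adjusted p = 0.229), DNA replication (adjusted p = 0.229) or histone (adjusted p = 0.253) lists. For mesenchymal, interferon and TGF-beta lists the median, mean and test did not share a sign.

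Growth genes again moved with MCF10A replicate 2. The mitotic list had a median of 2.50 and no member passed (adjusted p = 0.00848, and adjusted p = 0.755 with an estimated correlation), against 0.34 with 13 members higher without that library. MKI67, the proliferation antigen, measured 13930 ± 1110 in CA1 and 2815 ± 2400 in MCF10A (39.5 in replicate 2), at log2 3.96 with adjusted p = 0.0604. It had log2 1.73 (adjusted p = 3.87e-06) without replicate 2, and adjusted p = 0.035 and 0.0287 without replicate 1 or 3. DNA replication genes rose at 3 of 26 (adjusted p = 0.00709, and adjusted p = 0.755 with an estimated correlation), and at 0 adjusted over the list alone. Without that library 7 rose, the median was 0.27 in place of 1.261, and the list's call was lost (adjusted p = 0.0835). MCM2 (log2 2.06, adjusted p = 0.0214) and RFC4 (log2 1.91, adjusted p = 0.0187) lost their call without any 1 of the CA1 libraries (adjusted p up to 0.0627 and 0.0581).

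Histone genes rose at 7 of 21 and fell at 2 (adjusted p = 0.0409, and adjusted p = 0.755 with an estimated correlation), at 13 and 3 adjusted over the list alone. Without MCF10A replicate 2 they rose at 10 and fell at 3, and the call was lost (adjusted p = 0.234). Of 23 cholesterol synthesis genes 4 fell, such as TM7SF2 (log2 -1.03), and 1 rose (adjusted p = 0.115). TM7SF2 lost its call without any 1 of the CA1 libraries (adjusted p up to 0.0823). Without that library 20 cholesterol genes fell and the list was called (adjusted p = 6e-05, and adjusted p = 0.109 with an estimated correlation). Mitochondrially encoded mRNAs rose at 12 of 13 (adjusted p = 0.00011, and adjusted p = 0.395 with an estimated correlation), such as MT-ND1 to 2391 ± 102 (log2 2.30), and at 11 without that library. In CA1, mitochondrial rRNA took 0.565 to 0.706% of reads and RN7SK 0.425 to 0.517%. The limit on library preparation given for AT1 applies here too.

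In all, 7221 genes changed between CA1 and MCF10A by limma (3533 higher, 3688 lower), 366 of them lncRNAs (216 higher, 150 lower), and 353 lncRNAs did adjusted over the lncRNAs alone. The groups did not overlap for 55.2% of tested genes, against 10% by chance.

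**Figure D2:**
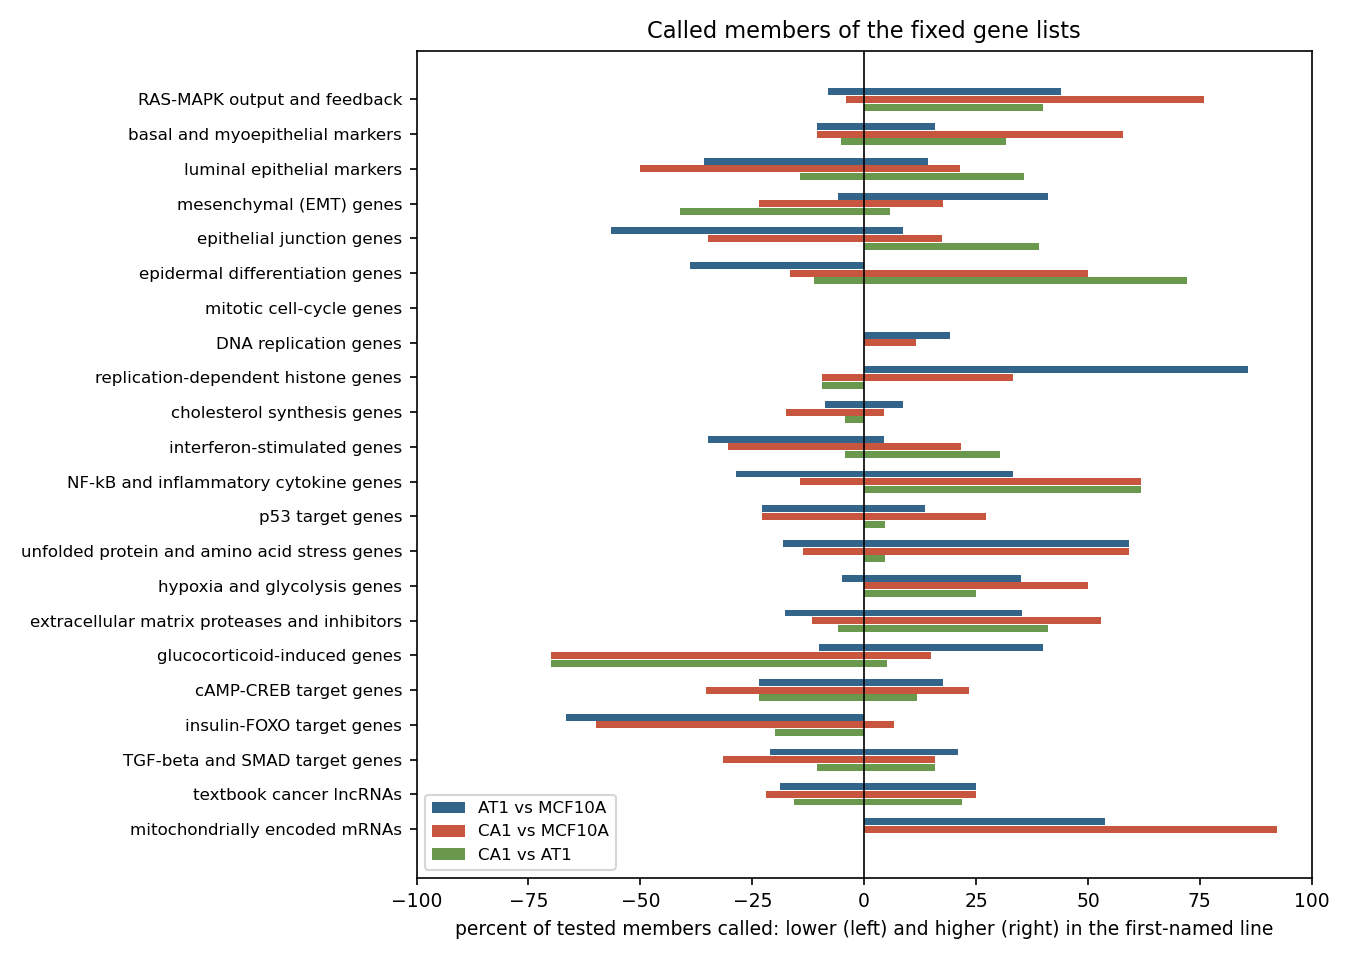
Percent of the tested members of each of 22 fixed gene lists that passed the test, lower to the left and higher to the right, in blue for AT1 against MCF10A, red for CA1 against MCF10A and green for CA1 against AT1. Junction genes were lower at 13 of 23 in AT1, and glucocorticoid-induced genes at 14 of 20 in CA1 against either line.

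The third comparison asked how CA1 differed from AT1. Here TMPRSS15 rose most (log2 10.36, ratio 2380, interval 812 to 11500), followed by CALML3 (at least 976-fold). BST2, an interferon-induced restriction factor, rose from 2.50 ± 0.373 to 1714 ± 85.7 (log2 8.94, adjusted p = 0.0055), SPARC from 5.68 ± 3.09 to 2681 ± 113 (log2 8.78), the mucosal keratin KRT13 from 4.89 ± 0.772 to 2474 ± 225 (log2 8.72), the neurotrophin receptor NGFR from 5.46 ± 2.74 to 1519 ± 217 (log2 7.98, adjusted p = 0.00823) and BMP7, a bone morphogenetic protein, from 1.22 ± 2.11 to 418 ± 44.3 (log2 7.97). PRSS21 rose 1490-fold (interval 268 to 59000).

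DCN, the matrix proteoglycan decorin, fell from 1730 ± 24 in AT1 to 0 in CA1 (at least 1920-fold, log2 -10.76). The folate enzyme ALDH1L2 fell from a mean of 900 to 2.59 ± 1.66 (log2 -8.10), and ZBTB16, a glucocorticoid-responsive transcription factor, from 547 ± 36.8 to 1.40 ± 1.22 (log2 -8.01). PDZD2 fell 1110-fold (interval 380 to 5390) and the estrogen sulfotransferase SULT1E1 976-fold (interval 334 to 4730). The linker histone H1-5 fell from 5712 ± 1080 to 1.51 ± 0.534 (log2 -11.16) and H2BC3 1320-fold (interval 452 to 6410), with the same doubt over similar histone copies. Among lncRNAs, FIRRE, which takes part in nuclear organisation, rose from 1.25 ± 0.186 to 186.8 ± 38 (log2 6.37), ZFPM2-AS1 from 2.69 ± 3.72 to 191.9 ± 5.95 (log2 6.23), LINC00973 at log2 6.39 and ELFN1-AS1 at least 83-fold. CAVIN2-AS1 (at least 60.9-fold), LINC01085 (at least 51.3-fold), FAM222A-AS1 (at least 32.7-fold) and LINC02381 (log2 -4.73) fell.

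Several lists of inflammatory and epithelial genes differed between CA1 and AT1. NF-kB and inflammatory genes rose at 13 of 21 with none lower (adjusted p = 2.15e-09, and adjusted p = 0.0645 with an estimated correlation), such as CXCL1 (log2 4.51) and IL1A (log2 3.95). Epidermal differentiation genes rose at 13 of 18 and fell at 2 (adjusted p = 8.23e-07, and adjusted p = 0.0645 with an estimated correlation), with the cornified-envelope gene SPRR2A at least 122-fold higher. Junction genes rose at 9 of 23 with none lower (adjusted p = 1.19e-05, and adjusted p = 0.0645 with an estimated correlation), with the tight-junction gene OCLN up from 44.4 ± 5.17 to 388.7 ± 32.9 (log2 3.11) and OVOL1 at log2 2.98. Basal markers rose at 6 of 19 and fell at 1 (adjusted p = 0.00443, and adjusted p = 0.139 with an estimated correlation), such as LAMB3 from 11730 ± 2000 to 42870 ± 3190 (log2 1.88) and TAGLN (log2 -3.26). Mesenchymal genes fell at 7 of 17 and rose at 1 (adjusted p = 0.000477, and adjusted p = 0.407 with an estimated correlation), with the repressor ZEB2 down from 713.8 ± 106 to 2.66 ± 0.526 (log2 -7.61) and FBN1 (log2 -4.53). Of 14 luminal markers 5 rose, such as KRT8 (log2 2.02), and 2 fell, such as MUC1 (log2 -5.17) (adjusted p = 0.148). In AT1 with the control GapmeR, normalised separately, junction medians were 3479, 3770 and 2357. They were 3615 to 3723 in CA1 and 1075 to 1271 in untransfected AT1. Luminal medians there were 1431, 1132 and 1610, above those of CA1 (681.8 to 776.6). So the junction and luminal rises in CA1 were not of this size against transfected AT1. Mesenchymal medians there (262.6 to 850.3) stayed above CA1 (116.2 to 129.5), and epidermal ones (73.53 to 212.8) below CA1 (301.8 to 343.1).

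RAS-MAPK genes rose at 10 of 25 with none lower (adjusted p = 2.12e-05, and adjusted p = 0.403 with an estimated correlation), such as the cytokine LIF from 247.5 ± 17.4 to 3773 ± 132 (log2 3.93) and TGFA (log2 2.27). Glucocorticoid-induced genes fell at 14 of 20 and rose at 1 (adjusted p = 2.15e-09, and adjusted p = 0.0645 with an estimated correlation), such as MAOA from 2464 ± 31 to 21.6 ± 2.1 (log2 -6.77) and the clock gene PER1 from 1575 ± 188 to 350 ± 54.1 (log2 -2.17). Matrix proteases and inhibitors rose at 7 of 17 and fell at 1, MMP28 (adjusted p = 0.00263, and adjusted p = 0.0645 with an estimated correlation), with SERPINB2 up from 6.43 ± 2.53 to 984 ± 6.27 (log2 7.11). Hypoxia and glycolysis genes rose at 5 of 20 (adjusted p = 0.00443, and adjusted p = 0.0645 with an estimated correlation), such as CA9 (log2 1.69) and HK2 (log2 1.53). Interferon-stimulated genes rose at 7 of 23 and fell at 1, IFI44L (log2 -4.08) (adjusted p = 0.00443, and adjusted p = 0.408 with an estimated correlation), with the RNA sensors RIGI (log2 1.55) and IFIH1 (log2 1.13) higher.

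Histone genes fell at 2 of 21 (adjusted p = 0.00182, and adjusted p = 0.662 with an estimated correlation). Of 23 cholesterol synthesis genes 1 fell, MVK (log2 -0.98) (adjusted p = 0.00182, and adjusted p = 0.633 with an estimated correlation), and MVK lost its call without AT1 replicate 3 (adjusted p = 0.0528) or CA1 replicate 1 (adjusted p = 0.0514). No mitotic gene (of 24, adjusted p = 0.984) or DNA replication gene (of 26, adjusted p = 0.824) passed, with CDK1 at log2 0.46 (adjusted p = 0.865) and MCM3 at log2 -0.47 (adjusted p = 0.533), and no mitochondrial mRNA of 13 did (adjusted p = 0.255). cAMP-CREB targets gave 2 up, with PTGS2 at log2 4.89, and 4 down, with PPARGC1A at log2 -5.06, of 17 (adjusted p = 0.984), and FOXO targets 3 down of 15 (adjusted p = 0.911), with PDK4 at log2 -2.36. In these cAMP-CREB and FOXO lists the test's sign was opposite to that of the median. TGF-beta targets rose at 3, with ITGB6 from 1926 ± 183 to 7434 ± 419 (log2 1.95), and fell at 2 of 19 (adjusted p = 0.567). Cancer lncRNAs rose at 7, with UCA1 at log2 4.09, and fell at 5, with H19 at log2 -4.40, of 32 (adjusted p = 0.567). A single p53 target of 22, TNFRSF10B (log2 0.74, adjusted p = 0.0114), and a single unfolded protein gene of 22, EDEM1 (log2 0.55, adjusted p = 0.0123), rose, with list p-values of 0.189 and 0.567. Both lost their call without AT1 replicate 3 or any 1 of the CA1 libraries (adjusted p up to 0.0586 and 0.0729).

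The MCF10A libraries, among them replicate 2 with its low growth genes, entered the spread used for these tests, although MCF10A is not compared here. A fit of only the CA1 and AT1 libraries, whose lists were examined after the data were seen, called more members: 7 mitotic genes higher and 3 lower (CDK1 at log2 0.46, adjusted p = 0.00757), 5 DNA replication genes higher and 7 lower (MCM3 at log2 -0.47, adjusted p = 0.000157), and 6 mitochondrial mRNAs higher and 1 lower. So the absence of calls in these lists does not show that they were alike. That fit gave 0 histone genes higher and 18 lower, 2 and 17 for cholesterol, 2 and 13 for mesenchymal, 17 and 0 for junction, 14 and 4 for basal, 8 and 5 for luminal, and 19 and 2 for RAS-MAPK genes. It gave 17 and 2 for NF-kB, 14 and 3 for epidermal, 14 and 1 for interferon, 11 and 4 for p53, 9 and 3 for unfolded protein, 11 and 1 for hypoxia, 9 and 4 for proteases, 6 and 5 for cAMP-CREB, 8 and 5 for FOXO and 10 and 5 for TGF-beta targets, and 13 and 9 for cancer lncRNAs. Glucocorticoid-induced genes, with 2 higher and 18 lower, kept their call in it (adjusted p = 0.0377 with an estimated correlation).

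In all, 2407 genes changed between CA1 and AT1 by limma (1523 higher, 884 lower), 107 of them lncRNAs (71 higher, 36 lower), and 86 lncRNAs did adjusted over the lncRNAs alone. The groups did not overlap for 57.2% of tested genes, against 10% by chance. Using only this pair's libraries gave 7898 genes and 333 lncRNAs, and leaving out an AT1 or CA1 library gave 1273 to 1483 genes.

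The series' own question was which lncRNAs are selective for 1 line. Of 886 tested lncRNAs, 120 (13.5%) were higher by at least 2-fold in 1 line than in each of the others, against 1962 of 15353 other genes (12.8%). With expression level taken into account, the odds ratio was 0.76 (0.62 to 0.93, adjusted p = 0.0338 over 4 tests), in a test across genes, which are not independent. No single line passed by that test (adjusted p = 0.13 for MCF10A, 0.13 for AT1 and 0.279 for CA1). The other genes include those with no class, some of which may be lncRNAs, so the shares and the odds ratio carry that limit. MCF10A had 75 such lncRNAs, the highest being NEAT1 (12630 ± 883), the scaffold of paraspeckles, OTUD6B-AS1 (1068 ± 389) and IGFL2-AS1. For IGFL2-AS1 this rests on untransfected AT1, since AT1 with the control GapmeR, normalised separately, measured 375.6, 505.1 and 776.7. AT1 had 5, led by LINC00665 (240 ± 25.1), CAVIN2-AS1 (52.3 ± 16.9) and LINC01085 (46.4 ± 9.22). CA1 had 40, led by LINC01819 (1006 ± 42.5), MIR222HG (736 ± 56.1), which hosts miR-221 and miR-222, and LINC00973 (574.7 ± 33.3).

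Calls were also counted across the AT1 and CA1 comparisons with MCF10A. Of genes called in each comparison, 2265 were higher in both and 2444 lower in both, 4709 in all, and 159 were opposite. Independent lists of these sizes would share 698 and 790. Since both comparisons use the same MCF10A libraries, part of the excess may come from those controls. In 3 forms of simulation with no line effect, the same-direction count was as large in 11, 0 and 16 of 100 draws. The covariance of the changes was 1.463, against simulated means of 0.297, 0.24 and 0.247 and highest draws of 2.091, 0.26 and 1.075. The changes correlated at 0.708, below the simulated medians of 0.922, 0.917 and 0.892. Without MCF10A replicate 2, 5947 genes moved the same way, with a covariance of 1.34.

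Markers of other cell types differed between the lines and between MCF10A libraries. Fibroblast markers in the table were 5 of 10: DCN measured 234.3, 1.412 and 116.2 in MCF10A, 1730 ± 24 in AT1, where mesenchymal genes rose, and 0 in CA1. POSTN, a matrix protein, measured 454.6, 0 and 126.4 in MCF10A, 253 ± 13.1 in AT1 and 0.672 ± 0.583 in CA1. The fibroblast protease FAP measured 905 ± 767 in MCF10A (22.6 in replicate 2), 671 ± 30.5 in AT1 and 540 ± 71 in CA1, and COL1A1 52.5 ± 11.7, 47.4 ± 15 and 77.4 ± 9.56. Haematopoietic markers were 3 of 10, with the monocyte gene CD14 at 982, 3785 and 468 in MCF10A, 277 ± 32.2 in AT1 and 11.2 ± 4.21 in CA1. LYZ measured 42.81 ± 42.1 in MCF10A, 0.488 ± 0.845 in AT1 and 2.83 ± 1.41 in CA1. ITGAM was highest in CA1, with 3.98 ± 6.35, 2.90 ± 2.89 and 17.35 ± 3.06. Endothelial markers were 3 of 10, with the adhesion gene PECAM1 at 592 ± 454, 74.8 ± 15.8 and 28.7 ± 6.9, and CDH5 at 166.6 in MCF10A replicate 2 against 9.76 and 4.45. KDR, the third of them, measured 866, 43.78 and 34.94 in MCF10A, 1.12 ± 1.1 in AT1 and 0.672 ± 0.583 in CA1. Of the IGFL family, 2 of 5 genes were in the table, and IGFL2 was below the mean needed for a test. IGFL1, a secreted ligand of this family, measured 5.00 ± 4.3, 8.91 ± 4.26 and 22.1 ± 5.81, higher in CA1 than MCF10A (log2 2.18, adjusted p = 0.0148), a call lost without CA1 replicate 1 (adjusted p = 0.0537) or 2 (adjusted p = 0.0545).

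The last comparison asked what changed in AT1 cells given the GapmeR against IGFL2-AS1. IGFL2-AS1 itself measured 552.5 ± 205 with the control (375.6, 505.1 and 776.7) and 339.6 ± 99.6 with its GapmeR (231.9, 358.4 and 428.5), at log2 -0.68 with adjusted p = 0.522, and adjusted p = 0.0113 with a replicate block. Its log2 change ran from -0.404 without control replicate 3 to -0.927 without control replicate 1. HRAS measured 3309 ± 245 and 2800 ± 385 (log2 -0.25, adjusted p = 0.612, and 0.0788 with the block). By limma without the block no gene passed, while 1742 had an unadjusted p below 0.05, edgeR called 0 and DESeq2 380. Libraries of the same number were correlated (0.611, 0.568 and 0.651), and with the replicate block 2528 genes changed, 986 higher and 1542 lower. Of these 19 were lncRNAs (2.1% of lncRNAs against 16.4% of other genes), and 1 lncRNA passed adjusted over the lncRNAs alone. With the block, that count was 665 without pair 2, 1820 without pair 1 and 3207 without pair 3, and 0 with no mean-variance trend. Groups did not overlap for 17.8% of genes, against 10% by chance.

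With the replicate block, VPS53, a subunit of a vesicle-tethering complex, fell from 716.7 ± 173 to 130.5 ± 24.7 (log2 -2.44, adjusted p = 0.000943), a larger fall than that of IGFL2-AS1 itself (log2 -0.68). With a single GapmeR against IGFL2-AS1, a response to its sequence and a response to depletion were not separable for VPS53 or any other gene here. The adhesion gene CDH13 fell from 964 ± 191 to 252 ± 95.8 (log2 -1.98), NGFR (log2 -2.06), the phosphatase EYA2 (log2 -2.37), the lipid carrier FABP4 (log2 -1.90) and the fragile-site gene FHIT (log2 -1.88) also fell. Rising genes included the channel gene CALHM5 from 8.91 ± 2.56 to 81.4 ± 34.5 (log2 3.01, adjusted p = 0.00318), the protease MMP7 from 222 ± 171 to 662 ± 251 (log2 1.76) and the lncRNA LINC01133 from 36.3 ± 5.79 to 133 ± 25.9 (log2 1.84). ACTBL2 (log2 3.29) and RPLP1 (log2 -2.11) have near-identical copies and are uncertain, as is RPS16 (log2 -2.36), whose call ended without pair 2 (adjusted p = 0.0617). Of 88 genes named with the block, 47 kept the call whichever pair was left out, 41 lost it without pair 2, 16 without pair 1 and 5 without pair 3.

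Interferon-stimulated genes were the only list called by camera with its preset correlation and all 6 libraries (25 tested, median log2 1.21, adjusted p = 9.24e-10, and adjusted p = 0.963 with an estimated correlation). Fry did not call it (adjusted p = 0.965, and adjusted p = 0.139 by its mixed test). Leaving out 1 library gave 1 to 5 lists, and leaving out a pair with the block 2 to 5. Without the block no member passed, and adjusted over the list alone 2 did. With the replicate block 12 rose and 1 fell, and adjusted over the list alone 21 rose. IFI27 rose from 140 ± 114 to 550 ± 137 (log2 2.23, adjusted p = 0.0143), as did IFI44 (log2 1.87, adjusted p = 0.0118). IFIT1, which binds viral RNA, rose from 339 ± 315 to 929 ± 314 (log2 1.87, adjusted p = 0.0277), a call that ended without pair 2 (adjusted p = 0.0879), and so did that of IFI44L (log2 1.87, 0.0898 without pair 2). By pair, the list's median was 1.417, 1.428 and 0.14, with 23, 24 and 13 of 25 genes higher. Control replicate 3 stood apart, with a median interferon level of 270.5 against 91.63 and 78.36 in the other controls, while the IGFL2-AS1 GapmeR libraries had 478.5, 443.4 and 388.1.

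**Figure D3:**
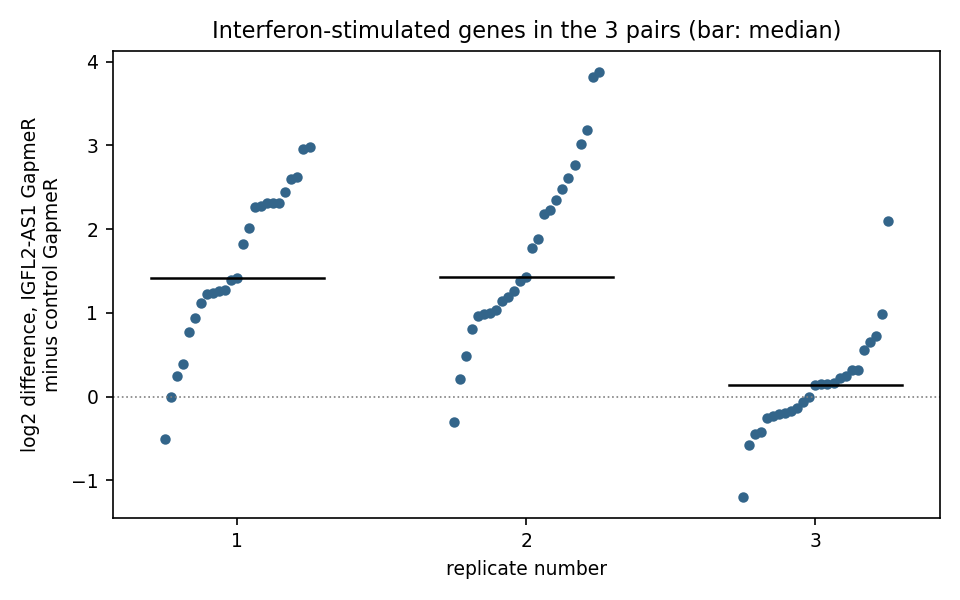
Log2 difference of IGFL2-AS1 GapmeR minus control GapmeR for 25 interferon-stimulated genes in each pair of libraries with the same replicate number, with dots for genes and bars for the median. Medians were 1.417, 1.428 and 0.14.

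No other list was called by camera with all 6 transfected libraries. Fry's mixed test, which ignores direction, called cholesterol synthesis genes (adjusted p = 1.14e-07, and adjusted p = 0.00191 with the block), proteases (adjusted p = 0.0311) and TGF-beta targets (adjusted p = 0.0311), and most lists with the block. The members below are those that passed with the replicate block. Growth-related lists were RAS-MAPK (1 up and 6 down of 25, ETV4 from 523 ± 145 to 240 ± 34.6 at log2 -1.09), mitotic (0 and 3 of 24, FOXM1 at log2 -1.19 and PLK1 at log2 -1.03), DNA replication (2 and 1 of 26), histones (0 and 0 of 21) and FOXO targets (0 and 1 of 15). The mitotic, DNA replication and histone lists ran in opposite directions by pair: mitotic genes were higher at 3, 13 and 21 of 24, DNA replication genes at 10, 13 and 25 of 26, and histones at 0, 8 and 19 of 21. Replicate 3 libraries stood apart, with mitotic medians of 1289 (control) and 1863, against 2872 to 3887 in the others. Epithelial lists were basal (5 and 5 of 19, KRT16 from 2297 ± 617 to 5357 ± 943 at log2 1.24), luminal (4 and 2 of 14, CD24 at log2 0.98), mesenchymal (1 and 4 of 17, MMP2 at log2 -1.25), junction (4 and 2 of 23, JUP at log2 -0.88) and epidermal (1 and 2 of 16, IVL at log2 -1.06). Stress and metabolic lists were cholesterol (9 and 4 of 23, IDI1 at log2 0.62 and LSS at log2 -0.60), p53 (2 and 2 of 22, XPC at log2 -0.63), unfolded protein (3 and 3 of 22, SLC7A5 at log2 -0.84), hypoxia (0 and 5 of 19, ALDOA at log2 -0.68) and mitochondrial mRNAs (2 and 4 of 13, MT-ND2 at log2 1.08 and MT-CO3 at log2 -1.59). Signal and matrix lists were NF-kB (2 and 1 of 17, BIRC3 from 3315 ± 941 to 6836 ± 870 at log2 1.08), proteases (2 and 5 of 17, TIMP3 from 2964 ± 529 to 1402 ± 42.1 at log2 -1.07), glucocorticoid (1 and 3 of 20, PER1 at log2 -1.05), cAMP-CREB (2 and 2 of 14), TGF-beta (3 and 3 of 19, PMEPA1 at log2 0.77) and cancer lncRNAs (2 and 1 of 33). IGFL1 measured 68.6 ± 47.1 and 96.2 ± 51.1 (adjusted p = 0.113 with the block).

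Genes called at least 2-fold higher (1801) or lower (2189) in AT1 than in MCF10A were followed in the transfected cells, where also tested there. The 1694 genes raised in AT1 had a mean log2 of -0.131 with the GapmeR (p = 0.0181, p = 0.517 with an estimated correlation, p = 0.497 by fry, a test of movement in 1 direction), and ranged from -0.24 without control replicate 3 (p = 6.69e-06 with the preset correlation) to -0.035 without control replicate 1 (p = 0.76). With the replicate block, 47 of these genes rose and 225 fell. The 1983 genes lowered in AT1 had a mean of 0.023 (p = 0.253, p = 0.819 with an estimated correlation, p = 0.9 by fry), ranging from -0.123 to 0.196 as libraries were left out. With the preset correlation, a call for these lowered genes appeared without control replicate 3 (0.196, p = 7.01e-06) and without IGFL2-AS1 GapmeR replicate 1 (0.142, p = 0.000959). With the replicate block, 202 of them rose and 157 fell.

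Across the lines, 13, 13 and 12 of 22 lists were called by camera in the 3 comparisons, and 1 in the transfected cells, against 14, 13, 11 and 0 by fry. None kept its call with an estimated correlation in the fits of all libraries, and other groupings of the same libraries called up to 15 lists and 0 genes.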

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

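Choices made before the data were examined were tried 1 at a time, and those on the blocked fit were chosen after seeing the data. For named genes, 4891 of 5017 values over 297 results kept their direction and side of the threshold, 91 lost a call, 35 gained one and none turned sign. For 22 summary results, 349 of 398 values stayed, 2 lost a call, 3 gained one and 44 were counts that moved by more than 1.5 times or to or from 0. A mean of at least 50 left fewer genes, with 150, 170 and 48 lncRNAs changed in AT1 against MCF10A, CA1 against MCF10A and CA1 against AT1, and 53 line-selective lncRNAs. A 2-fold threshold kept 3990 and 4390 genes in the comparisons with MCF10A. Fits on only the libraries compared gave 4141 genes and 189 lncRNAs for AT1 against MCF10A, and 7898 and 333 for CA1 against AT1. Leaving out a library gave 4416 to 8206 genes and 206 to 373 lncRNAs for AT1 against MCF10A, and 1273 to 1483 genes and 61 to 70 lncRNAs for CA1 against AT1. With an estimated correlation 0 lists were called in any of the 4 comparisons, and with fry 0 in the transfected cells. In the transfected cells, DESeq2 called 380 genes and 1 lncRNA, and the replicate block 2528 genes and 19 lncRNAs, with IGFL2-AS1 at -0.68 and adjusted p = 0.0113 (0.0113 to 0.808 over all alternatives, with log2 changes from -0.927 to -0.404). Apart from single genes, the block changed no call by camera or by fry's directional test there, while fry's mixed test called most lists with the block. Lists called there numbered 5, 4 and 5 without control replicate 1, 2 or 3, and 1, 3 and 5 without GapmeR replicate 1, 2 or 3. Genes raised in AT1 had means from -0.24 to -0.035 there, and genes lowered in AT1 from -0.123 to 0.196. With the block, no mean-variance trend gave 0 genes, and leaving out a pair gave 665 to 3207 genes and 4, 2 and 5 lists. In the lines, replicate numbers paired weakly at most (same-number correlations from -0.029 to 0.189). CA1 replicate 3 was at 0.012 with MCF10A, against 0.116 for another number. AT1 replicates 1, 2 and 3 were at 0.178, 0.098 and 0.106 with MCF10A, against -0.037, 0.029 and -0.01 for other numbers. With the replicate block, the lines gave 6732, 7311 and 2282 genes and 305, 344 and 84 lncRNAs. Rescaling left the median over all genes within 0.049 of 0. The cause of these differences was not tested where fewer genes or libraries do not account for them.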

Other observations

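Transcripts of the imprinted region of chromosome 15 set the lines apart. SNHG14, the host of the small nucleolar RNAs of that region, measured 0 in MCF10A, 316.9 ± 50.6 in AT1 (at least 326-fold) and 445 ± 32.9 in CA1 (at least 442-fold). PWAR5 measured 0 in MCF10A and 83.7 ± 28.8 in AT1 and was at least 99.4-fold higher in CA1, and SNRPN, a splicing protein gene, rose from 0 to 58.3 ± 4.06 in AT1. These genes overlap SNHG14, so their reads may be shared. EMD, which encodes the nuclear envelope protein emerin on the X chromosome, measured 607 ± 159 in MCF10A and 735.9 ± 56.9 in AT1 and was lower in CA1 by 2420 times (interval 434 to 95500, log2 -9.19). In CA1, relative to AT1, the median gene lay at 0.254 to 0.285 on chromosome 2, 0.247 to 0.285 on chromosome 3, 0.158 to 0.212 on chromosome 10 and 0.331 to 0.37 on chromosome 20. BST2 measured 1.4, 606 and 31.1 in the MCF10A libraries.

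Transfected AT1 cells differed from untransfected AT1 cells, and levels set across these separately normalised tables carry that limit. IGFL2-AS1 measured 62.9, 45.1 and 56.3 in untransfected AT1 and 375.6, 505.1 and 776.7 with the control GapmeR. DCN measured 153.8, 3.18 and 1858 with the control GapmeR and 217.9, 4.30 and 1749 with the IGFL2-AS1 GapmeR, in replicate order. VIM measured 1683, 2012 and 11080, then 1227, 969 and 7521. Reads of mitochondrially encoded genes made up 0.7%, 0.246% and 0.378% with the control, and 0.212%, 0.115% and 0.295% with the IGFL2-AS1 GapmeR.

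The following tests of the pattern in MCF10A replicate 2 were chosen only after the result was seen. Its mitotic genes lay a median of -5.912 log2 units from replicates 1 and 3, with 24 of 24 lower, while the lowest of 10000 lists matched for expression lay at -1.032, so scaling or a few abundant RNAs would not give this. A swap with an AT1 or CA1 library would place an MCF10A-like chromosome 9 median in those groups, and the nearest such library lay 0.622 away. An earlier form of that test, which asked for 80% of separating genes to lie nearer MCF10A, gave 79.9% over 3982 genes and missed its bound, and the chromosome test was added after. Fewer cycling cells in this culture may account for the pattern, since 26 DNA replication genes, which share no gene with the mitotic list, were lower by a median of -2.59, all 26 of them.

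Tests of whole-chromosome shifts between the lines were also chosen only after the result was seen. In MCF10A libraries, relative to AT1, the median gene of chromosome 7 lay at 0.452, 0.564 and 0.505, that of chromosome 8 at 0.583, 0.463 and 0.529, and that of chromosome 9 at -0.659, -0.651 and -0.679. On these 3 chromosomes 100% of 22 windows of 20 Mb moved in their chromosome's direction, against a single region as the source, while the spread between MCF10A libraries, at most 0.259 of the shift, decides nothing, since the chromosomes were picked after these values were seen and chromosomes 16 (0.254, 0.531 and 0.367), 19 (-0.42, 0.049 and -0.144) and 22 (-0.421, -0.035 and -0.181) varied between MCF10A libraries about as much as they shifted. Differences in chromosome copy number could give these shifts, with 72.7% of windows (16 of 22) within the range set for it. A bias that varies by library, or that all libraries of a line share, cannot be told apart from it, although the AT1 libraries of the transfected cells, normalised separately, lay within 0.155 of the AT1 medians.

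For interferon genes in the transfected cells, tests were chosen only after the result was seen as well. In pairs 1 and 2 the list's median was at least 1.417, above every one of 10000 matched lists, so scaling would not give it. An effect in every pair was not seen, since pair 3 gave 0.14, a value that 8.78% of matched lists reached, with a control library already at a median level of 270.5. A response to the oligonucleotide sequence might raise these genes, and with 1 GapmeR, at which IGFL2-AS1 had log2 -0.68, this cannot be told apart from an effect of depletion.

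Other groupings of the libraries were chosen as tests before the data were examined. With 10 splits of 6 libraries a share below 0.05 is out of reach, and the real counts beside the highest other were 6689 and 0 genes, 324 and 0 lncRNAs and 13 and 15 lists for AT1 against MCF10A, where 2 splits called as many lists. For CA1 against MCF10A they were 7221 and 0, 366 and 0, and 13 and 10, and for CA1 against AT1 2407 and 0, 107 and 0, and 12 and 12, again 2 splits. In the transfected cells they were 0 and 0 genes and 0 and 0 lncRNAs, so that all 10 splits tie, and 1 and 10 lists, where 9 splits called as many. Genes raised in AT1 had a mean of -0.131 against a highest other of 0.261 in size, with 4 of 10 splits as large, and genes lowered in AT1 0.023 against 0.397, with 9 of 10. With the block, 1 of 4 splits that part all pairs reached 2528 genes, with 0 as the highest other. Over 100 splits of the 9 libraries, only 1, the real one, gave 120 line-selective lncRNAs (highest other 62). In 3 forms of simulation with no line effect, run after the result was seen, the counts reached at most 81, 4 and 95. Other groupings mix the lines, which widens the spread within groups and lowers their counts. The simulated noise came from replicates that may be technical, in 100 draws each, so chance is not excluded for that count. The real grouping alone also gave 4709 shared genes (highest other 3561), but simulations with no line effect reached this in 11, 0 and 16 of 100 draws, so that chance is left open for the shared genes. Splits of the transfected libraries called up to 10 lists with the preset correlation, and those of the lines up to 15. The source of these calls was not tested.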
